A study of Mus musculus with 4 samples.

How the data were processed

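Gene expression was measured by RNA sequencing in cultures of naive mouse CD4+ T cells, and 4 libraries were analysed. Per the labels' protocols, the RNA was total RNA and the libraries were made with a TruSeq RNA kit. Per the series description, they were read on an Illumina MiSeq. Each file was a table of 37583 features with several read counts per feature, made by the authors before deposit. The unit used was the deposited count of total exon reads, a whole number with no normalization, in which a read that fits several places also counts. The mouse build was mm9 and CASAVA 1.8.2 was used, per the submitters' processing notes, while the aligner, the gene annotation and the counting rule were not given in the sources used here. A feature without an exon length held no exon reads, and there were 9551 such features. The strand of the reads was not given in the sources used here. Mitochondrial transcripts were not analysed here.

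The labels name a control library for each inhibitor, so DMAT was set against its own control and CX4945 against its own. Each of the 4 groups held 1 library. Nothing in the labels says that the 2 pairs are separate cultures from separate animals, so p-values measure the spread between these libraries, which may be technical. The control library of one pair was also set against that of the other, as a background of the same measure that includes the difference between the experiments. No duplicate library was found: between any 2 libraries the chi-square of the counts per degree of freedom lay between 2.56 and 5.63.

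Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3), which lay between 0.99 and 1.009, and log2 ratios of CPM (reads divided by the scaled library size, on the usual CPM scale) used a prior count of 2. A gene entered a pair with at least 20 reads in its 2 libraries and was counted when it was at least 2-fold higher or lower. With 1 library per arm these ratios have no replicate check and carry no p-value. Intervals on ratios are exact conditional (Clopper-Pearson) 95% intervals, and intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 was given a floor of 3 counts, which is 1.08 to 1.47 CPM per library. The number of 2-fold genes that counting error alone gives was taken from 100 binomial draws per pair.

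Both experiments were then fitted together, with the pair as a block, by edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment over 9629 genes. The SE given with a joint log2 fold change was computed as its absolute value divided by the square root of the F statistic. It is not a spread between replicates. The pairing comes from the titles. Across 6968 genes with at least 200 reads, the difference between the experiments in the control libraries correlated with that in the inhibitor libraries (Pearson's r = 0.418), a correlation across genes, which are not independent replicates. This fit leaves 1 residual degree of freedom per gene, which is the disagreement between the 2 inhibitors. The fitted dispersion was shared across genes with 19.7 prior degrees of freedom, so most of a gene's spread was taken from other genes. All 54 called genes had the same sign with both inhibitors, but a call does not show that the sizes agree. Timp1 passed with log2 ratios of -3.80 with DMAT and -0.85 with CX4945, and Ms4a4b with 1.98 and 0.73. In 10 simulated data sets for this joint comparison, over 9634 genes with 200 changed each, the fit recovered 44.3% of genes changed 1.5-fold, 82.5% changed 2-fold and 96.2% changed 4-fold, and 3.46% of its calls were false. In the same data the fit without the block recovered 33.0% of genes changed 2-fold and DESeq2 38.7%, with 0% false calls in each. The simulated counts had 1 dispersion for all genes, 0.00598 from the blocked fit, and the same change with both inhibitors. They held no gene-specific spread and no disagreement between the inhibitors. These shares therefore hold for that setting alone and do not rank the fits on the real data. The ratio interval was tested on simulated data for DMAT against its control and held the true ratio of 2 in 95.7% of 5000 draws.

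Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of 37 lists, 31 had at least 3 genes in the joint fit. Per inhibitor, a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Tested on independent random normal values in place of log2 ratios, 7.5% of 200 random lists fell outside the central 95%. Such values have no link to expression or between genes, so this does not check the matching or the effect of gene correlation. Over both experiments camera (limma 3.58.1) was run with a preset correlation of 0.01 and BH adjustment over lists. Of the 12 lists past an adjusted p of 0.05, 0 held with an estimated correlation. With that option camera uses the 1 residual degree of freedom of the fit, so hardly any list could pass. The Th17 list had an estimated correlation of -0.0292, yet its unadjusted camera p went from 2.72e-15 to 0.0737. The loss of the calls therefore does not show what correlation between genes does to them, and the calls rest on the preset value. Mitosis, Th1 and encephalitogenic effector genes had estimates of 0.75, 0.556 and 0.5, far above the preset 0.01. The other lists among the 12 had 0.0294 or less. These estimates too rest on 1 residual degree of freedom.

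Named genes follow a fixed rule. Per inhibitor these are the 10 highest and the 10 lowest genes with the same sign in the other inhibitor and at least 30 reads in the larger library, and the 3 highest and 3 lowest without the sign condition. From the joint fit they are the 12 largest changes in each direction, and from each list up to 4 members with the largest mean log2 ratio. Il17a, Il17f, Il23r, Foxp3, Il2, Csf2, Il10 and the CK2 subunits were among the genes always included. Not every gene that the rule takes in is described here, though all of them entered the counts and tests. Predicted genes, receptor segments and small RNAs were left out. Where less than 50% of a named gene's reads were unique, that share is given with the gene. DESeq2 1.42.0 was used as an alternative test. Other alternatives were another scaling, other prior counts, other read minimums, other controls, no block and leaving out each library. Unique exon reads, and for the joint fit scaling to the total count, were added after seeing the data. Ribosomal RNA was searched for with blastn 2.17.0 among GENCODE transcripts of the GRCm38 build that are annotated as ribosomal RNA. Transcripts of the gene Gm42418 were added to that set by name. Figures were drawn with matplotlib 3.10.9.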

Results

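The study asked what inhibition of CK2, a serine/threonine protein kinase, does to the transcriptome of T helper cells driven towards the Th17 fate. Naive CD4+ T cells from mouse spleen were stimulated through CD3 and CD28 for 24 h with IL-1β, IL-6 and IL-23 and with antibodies that block IL-4 and IFN-γ, a culture the labels call aTh17. One library comes from cells that received 1.5 µM DMAT and another from cells that received 1 µM CX4945, both inhibitors of CK2, and the labels name a control library for each. The 4 libraries held 2772525 exon reads (control for DMAT), 2523446 (DMAT), 2285545 (control for CX4945) and 2056635 (CX4945). Between 9331 and 9661 genes had at least 10 reads. The inhibitors differ in dose and in experiment as well as in compound, so a difference between their values was not tested.

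Transcripts of the enzyme itself were at similar levels. The catalytic subunits Csnk2a1 and Csnk2a2 and the regulatory subunit Csnk2b had log2 ratios of -0.12, 0.08 and 0.00 with DMAT and 0.12, 0.07 and 0.07 with CX4945. In the joint fit none passed the test (edgeR quasi-likelihood, BH adjusted p = 0.998, 0.963 and 0.981).

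With DMAT the Th17 cytokine genes Il17f and Il22 were lower than in the control. Il17f, the Th17 cytokine on chromosome 1 (mm9, 20767232 to 20774351), was at 377 CPM in the control and 51.5 CPM with DMAT, 7.34-fold lower (95% counting interval 6.11 to 8.87). The receptor gene Il23r was 6.13-fold lower (3.61 to 11.1), and Il22, a cytokine gene with 62 reads in the control and 0 with DMAT, was at least 19.0-fold lower against the floor of 3 counts, and at least 14.96-fold by its 95% counting interval (45.7% of its reads were unique). Gpr83, a receptor expressed by regulatory T cells, was 3.79-fold higher (2.67 to 5.48).

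Among the other genes lowest with DMAT were Il1rn, the IL-1 receptor antagonist, with 54 reads in the control and 1 with DMAT (ratio 0.0202, 0.000502 to 0.117), and the metalloproteinase inhibitor Timp1, with 106 and 5 (35.0% unique). The inhibitory receptor Tigit was 6.42-fold lower (3.29 to 14.0) and the IL-18 receptor subunit Il18rap 5.2-fold lower (2.16 to 15.1). Lum (lumican) had 39 reads in the control and 6 with DMAT, and Ildr1 had 31 and 3 (ratio 0.105, 0.0206 to 0.338). At the other end, Ms4a4b was 4.15-fold higher (2.77 to 6.38), the cytokine gene Il16 2.8-fold (2.0 to 3.98, with 37.8% of reads unique), the ubiquitin ligase gene Rnf157 2.63-fold (1.98 to 3.51), Ephb6 2.86-fold (1.7 to 4.97), Mnd1 3.6-fold (1.73 to 8.19) and Tbc1d30 3.38-fold (1.61 to 7.73). Dpm1 was 5.52-fold higher (3.2 to 10.1), but just 3.52% of its reads were unique. Between the control libraries Dpm1, Ms4a4b and Tbc1d30 were higher in that for CX4945, by log2 1.61, 1.73 and 1.05, and Il1rn, Lum and Ildr1 lower, with -1.02, -1.10 and -1.09. Lars2 was 2.91-fold higher (2.5 to 3.39) and AY036118 2.79-fold (2.13 to 3.68). Of 9649 genes, 105 were at least 2-fold higher and 123 at least 2-fold lower. Counting error alone gave 44.6 such genes on average. The control libraries differed from each other at 216 of 9564 genes, 94 higher and 122 lower in the control for CX4945. The count of 2-fold genes with DMAT is of similar size. The controls belong to different experiments, so their count also carries that difference and may overstate the background within a pair.

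With CX4945 the same cytokine genes were among the lowest. Il17f was at 263 CPM in the control and 65.8 CPM with CX4945, 3.99-fold lower (3.3 to 4.85), and Il22 was 3.16-fold lower (1.95 to 5.33). Il17a, on the same chromosome at 20720986 to 20724577, had 22 reads in the control and 1 with CX4945 (ratio 0.051, 0.00124 to 0.316), and 22 and 3 reads in the DMAT pair (ratio 0.149, 0.0285 to 0.495). Klf2, a transcription factor of resting T cells, was 3.19-fold higher (1.86 to 5.7).

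Other genes lowest with CX4945 were Slc4a11, 3.0-fold lower (1.5 to 6.51), the glycosyltransferase B3gnt2, 3.12-fold (1.51 to 7.06, with 18.5% of reads unique), the fatty acid desaturase Fads2, 3.07-fold (1.43 to 7.33), Tymp, 2.97-fold (1.38 to 7.11), the granzyme inhibitor Serpinb9, 2.57-fold (1.45 to 4.76), and Ccdc15, 2.62-fold (1.46 to 4.95). Fads2 differed more between the control libraries, with 160 reads in that for DMAT and 31 in that for CX4945, and Klf2, Agpat2 and Zfp322a also differed there, by log2 1.30, -1.04 and -1.04. Cyp1a1, a xenobiotic-metabolising enzyme and AhR target, was 2.59-fold higher (1.31 to 5.41), Agpat2 4.74-fold (2.25 to 11.1, with 22.9% of reads unique), Tcp11l2 2.81-fold (1.4 to 6.02), Ms4a6c 2.24-fold (1.2 to 4.38) and Pus3 2.35-fold (1.38 to 4.1, with 15.8% unique). Lars2 was 3.42-fold higher (3.0 to 3.91) and AY036118 3.07-fold (2.31 to 4.11). Nrm was 3.59-fold higher, Zfp322a 2.38-fold higher and Rpsa-ps12 2.91-fold lower, with 11.0%, 9.59% and 2.48% of their reads unique. Of 2 loci under the symbol Lrch4 on chromosome 5, the one that starts at 138070349 had a log2 ratio of -1.29 with 1.42% of reads unique, and the other had the opposite sign. Of 9358 genes, 83 were at least 2-fold higher and 86 at least 2-fold lower, where counting error alone gave 51.3. That total is below the 216 found between the controls, and it became 364 with the other inhibitor's control and 108 with unique reads.

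**Figure D1:**
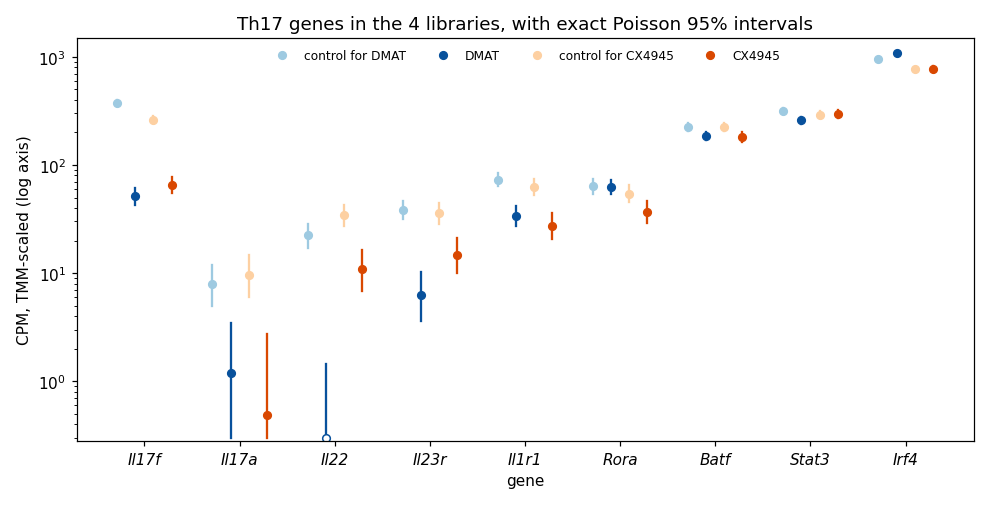
TMM-scaled CPM on a log axis of 9 Th17 genes, chosen after their values were seen, with a point per library, exact Poisson 95% intervals (counting error only) that run off the lower end of the axis for Il17a, and an open point there for the 0 reads of Il22 with DMAT. Il17f lies at 377 and 263 CPM in the controls and at 51.5 and 65.8 CPM with the inhibitors.

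Of 9262 genes that entered both pairs, 14 were at least 2-fold lower with both, where independent lists would share 0.907. They were Il17a, Il17f, Il22, Il23r, the IL-1 receptor gene Il1r1, Il1rn, Il18rap, Tigit, Rpsa-ps12, Gatm, H1f0, Marcks, Gm14230 and Rpl27a-ps1, the last 5 named after their values were seen. Of these 14 genes 5 are on the Th17 list, and no enrichment was tested. The 4 genes higher with both (0.518 if independent) were Lars2, AY036118, P2ry10 and Gm6476, of which P2ry10 and Gm6476 were named after their values were seen. Asf1a and Gm5601 were higher with DMAT and lower with CX4945 (2 genes, 0.58 if independent), and Il1rap, Lgals3, Tsix, Gm10521 and Gm6644 the reverse (5 genes, 0.81), all 7 named after their values were seen. The overlaps in opposite directions were thus above their independent values too. Those values give every gene the same chance of reaching 2-fold, whatever its read count, so they may be too low. Against the mean of both controls, a reference that both ratios then share, 29 genes had the same direction in place of 18. Across all 9262 genes the log2 ratios were weakly related (Pearson's r = 0.12, Spearman's rho = 0.0736), and genes are not independent replicates.

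**Figure D2:**
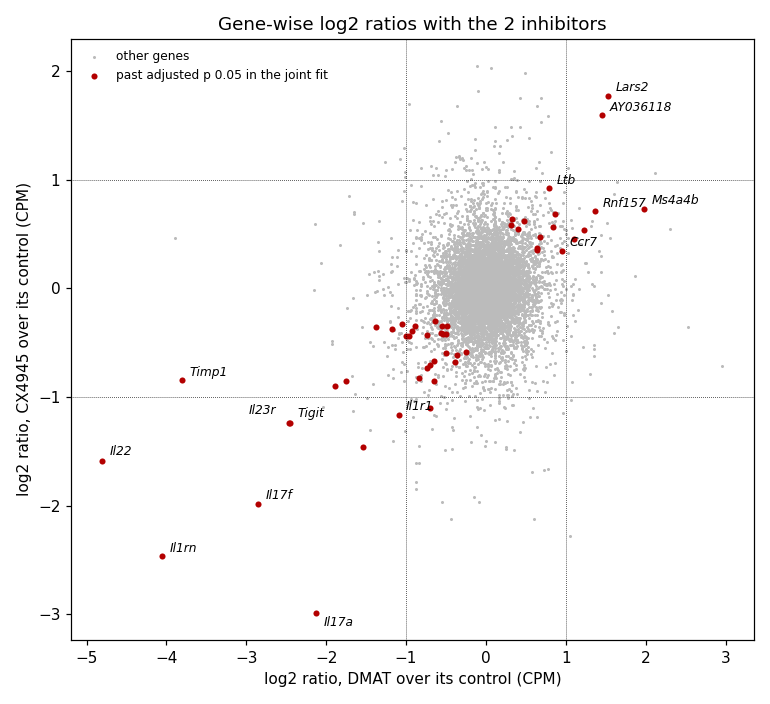
Log2 ratio of each of 9262 genes with DMAT (horizontal axis) and with CX4945 (vertical axis), each over its own control, with dotted lines at 2-fold. Red points are genes past an adjusted p of 0.05 in the joint fit, and Il17f, Il17a, Il22, Il23r and Il1rn lie in the lower left, Lars2 and AY036118 in the upper right.

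When both experiments were fitted together, 5 of the 19 Th17 genes tested fell and 3 of the 16 naive and quiescence genes rose, while the other genes of these lists did not pass. Il17f fell with a log2 fold change of -2.45 ± 0.15 (SE; edgeR quasi-likelihood, BH adjusted p = 1.63e-09), Il23r with -1.89 ± 0.30 (0.00326), the IL-1 receptor gene Il1r1 with -1.15 ± 0.17 (0.00203), Il22 with -2.61 ± 0.48 (0.0132) and Il17a with -3.25 ± 0.65 (0.0186). In mm9 Il23r lies on chromosome 6 (67372926 to 67441849), Il1r1 on chromosome 1 (40281925 to 40373043) and Il22 on chromosome 10 (117641998 to 117647098). Il1rn, Tigit, Timp1, Lum and Ildr1 fell too, with adjusted p of 0.00148, 0.0135, 0.0186, 0.0193 and 0.0378. Ccr7, a chemokine receptor of naive T cells, rose by log2 0.67 ± 0.12 (adjusted p = 0.0132).

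Further genes that fell were Frmd4b (log2 -1.41, adjusted p = 0.00356), the TNF receptor family gene Tnfrsf8, which encodes CD30 (-1.26, 0.0204), the NF-kB inhibitor Tnfaip3 (-0.55, 0.0135), the transcription factor Klf6 (-0.72, 0.0193), the oxygen-sensing hydroxylase Egln3 (-0.68, 0.0288), the glycolytic enzymes Hk2 (-0.53, 0.0146) and Tpi1 (-0.41, 0.0363), and the mitotic cyclin Ccnb1 (-0.64, 0.0213, with 43.7% of reads unique). Rpsa-ps12 fell as well, with 2.48% of its reads unique, too few for a test with unique reads. Genes that rose were Lars2, the mitochondrial leucyl-tRNA synthetase on chromosome 9 from 123276058 to 123371782 (1.66 ± 0.10, 1.96e-09), AY036118 on chromosome 17 from 39985048 to 39985772 (1.55 ± 0.16, 2.17e-05), Igfbp4 (0.78, 0.000868), the histone deacetylase Hdac7 (0.58, 0.00346), the phosphatase Ptprs (0.72, 0.00534), the lymphotoxin gene Ltb (0.88, 0.0132, but -0.0263 without the CX4945 library and the block), Ms4a4b (1.27, 0.0132), Rnf157 (1.12, 0.0132), Aff3 (0.82, 0.0144), Trib2 (0.54, 0.0193) and Tcf7, a transcription factor of naive T cells (0.49, 0.0144, with 16.1% of reads unique). The AY036118 transcript matched a transcript in the set searched for ribosomal RNA. The exon-exon reads of Lars2 were 1.44 times as frequent with the inhibitors (0.893 to 2.34) against 3.3 times for its other exon reads (2.98 to 3.65). Ltb and Ms4a4b also differed between the control libraries, by log2 1.36 and 1.73 (control for CX4945 over that for DMAT). So did Igfbp4, Lars2, Tcf7 and Trib2, by 0.70, 0.61, 0.42 and -0.445. Il2, which encodes the T cell growth factor IL-2, did not pass the test (adjusted p = 0.59). Foxp3 had 4, 3, 2 and 3 reads (25.0% unique) and Il10 had 1 in every library, so differences in them were not detectable at this depth, and Csf2 had 4 reads in a library at most.

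In all, 54 genes passed among 9629 tested, of which 17 rose and 37 fell, and 696 had an unadjusted p under 0.05. The count depends on the fit: without the block 1 gene passed, Il17f (adjusted p = 0.0192), and DESeq2 with the block called 3, Lars2, AY036118 and Il17f. With DESeq2 size factors in edgeR 84 passed, of which 35 rose and 49 fell, with total-count scaling 101 and with unique reads 108 (45 rose and 63 fell). In fits without the block that left out each library in turn, most of the 54 calls were lost whichever library was left out. Such a fit leaves 1 library in an arm, so its count of passing genes is not given.

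The fixed Th17 list shifted down (camera adjusted p = 8.43e-14; adjusted p = 0.665 with an estimated correlation). Of its 19 tested genes 5 fell, 0 rose and 14 did not pass, against 8 that fell and 1 that rose when adjusted over the list alone. With both inhibitors 9 were lower and 6 higher, and 4 had opposite signs. The median log2 ratio was -0.10 with DMAT, inside the central 95% of matched random lists, -0.21 with CX4945 and -0.10 between the controls, while the mean was -0.73 with DMAT and -0.46 with CX4945. Batf, an AP-1 family transcription factor of the Th17 programme, had log2 ratios of -0.27 and -0.30 and did not pass (adjusted p = 0.357). The encephalitogenic effector list shifted down (camera adjusted p = 6e-08, and 0.665 with an estimated correlation of 0.5). Il1r1 and Il23r fell among its 8 genes, and 3 fell when adjusted over the list alone. Its median was -1.18 with DMAT and -0.18 with CX4945, 3 of the 8 genes were lower with both inhibitors and 5 had opposite signs. Il1r1 and Il23r are also on the Th17 list, and Stat4 and Tbx21 also on the Th1 list. The shifts of these lists are therefore not separate results. The STAT3 and IL-6 target list did not pass the test (0.538), and its medians were -0.10 with DMAT and 0.00 with CX4945.

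The Th1 list shifted down (camera adjusted p = 2.36e-07, and 0.665 with an estimated correlation of 0.556). Over all genes 0 of its 9 genes passed, and 5 fell when adjusted over the list alone. Its median was -1.04 with DMAT and -0.35 with CX4945. Stat4, the IL-12 signalling factor, stood at -1.05 and -0.50 (adjusted p = 0.0521), and Tbx21, the Th1 master regulator, at -1.46 with DMAT and 0.13 with CX4945. The Tfh list shifted down (0.0174; adjusted p = 0.665 with an estimated correlation) with medians of -0.32 and -0.22, 0 of 8 genes passing and 1 falling when adjusted over the list alone. The Treg list shifted up (0.0273; adjusted p = 0.665 with an estimated correlation), with medians of 0.66 and 0.11, 0 of 9 genes passing over all genes, and 2 rising and 1 falling when adjusted over the list alone. The controls differed by 0.25 in this list, and against the other inhibitor's control the median with DMAT was -0.0849. Its members Gpr83 and Tnfrsf18, which encodes GITR (25.1% of reads unique), stood at 1.87 and 1.01 with DMAT and 0.11 and 0.40 with CX4945, while Foxp3 was near the floor. The Th2 list did not pass the test (0.78), with medians of 0.30 and -0.24.

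The list of naive and quiescence genes shifted up (1.04e-08; adjusted p = 0.665 with an estimated correlation). Of 16 tested, 3 rose, with Ccr7 and Tcf7 among them (the call of Tcf7 was lost with unique reads), and 0 fell, or 6 rose when adjusted over the list alone, and the medians were 0.46 with DMAT and 0.21 with CX4945. The control for CX4945 was also higher than that for DMAT in this list, by a median of 0.30, and against the other inhibitor's control the median with DMAT was -0.0407. Mitotic genes shifted down (camera adjusted p = 4.37e-13, and 0.665 with an estimated correlation of 0.75). Their medians were -0.42 and -0.20, and 14 of 16 were lower with both inhibitors. Ccnb1 alone fell over all genes, a call lost with unique reads, and 12 fell when adjusted over the list alone, but the controls differed by -0.33 as well. Plk1, a mitotic kinase, stood at -0.79 and -0.30 (adjusted p = 0.1), and Bub1, a spindle checkpoint kinase, at -0.52 and -0.54 (0.095). Glycolysis genes shifted down (5.61e-08; adjusted p = 0.665 with an estimated correlation), with medians of -0.13 and -0.25, Hk2 and Tpi1 falling among 17, and 4 falling when adjusted over the list alone. Hypoxia genes shifted down (0.0061; adjusted p = 0.665 with an estimated correlation), with medians of -0.11 and -0.15 and -0.28 between the controls. Egln3 fell among 13 genes, also when adjusted over the list alone, while Bnip3 did not pass (adjusted p = 0.498), at 1.38-fold lower with DMAT (0.907 to 2.11) and 5.79-fold lower with CX4945 (2.01 to 22.8), with 26 and 4 reads. ATF4 stress genes shifted down (0.000286; adjusted p = 0.665 with an estimated correlation), with 0 of 13 genes passing, also when adjusted over the list alone, and medians of -0.29 and -0.04, while the controls differed by -0.40 and the median with DMAT was 0.127 against the other inhibitor's control. NF-kB target genes shifted down (0.0159; adjusted p = 0.665 with an estimated correlation), with medians of -0.22 and -0.10, and Tnfaip3 fell among 14, also when adjusted over the list alone. T cell identity genes shifted up (0.0159; adjusted p = 0.665 with an estimated correlation), with a median of 0.13 with DMAT (-0.0543 against the other inhibitor's control), 0.00 with CX4945 and 0.17 between the controls, 0 of 14 passing over all genes and 1 rising when adjusted over the list alone. Of the 12 lists that shifted, the hypoxia list had both its medians inside the central 95% of matched random lists, the Th17 list that with DMAT, and the encephalitogenic effector, Treg, ATF4, NF-kB and T cell identity lists that with CX4945.

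**Figure D3:**
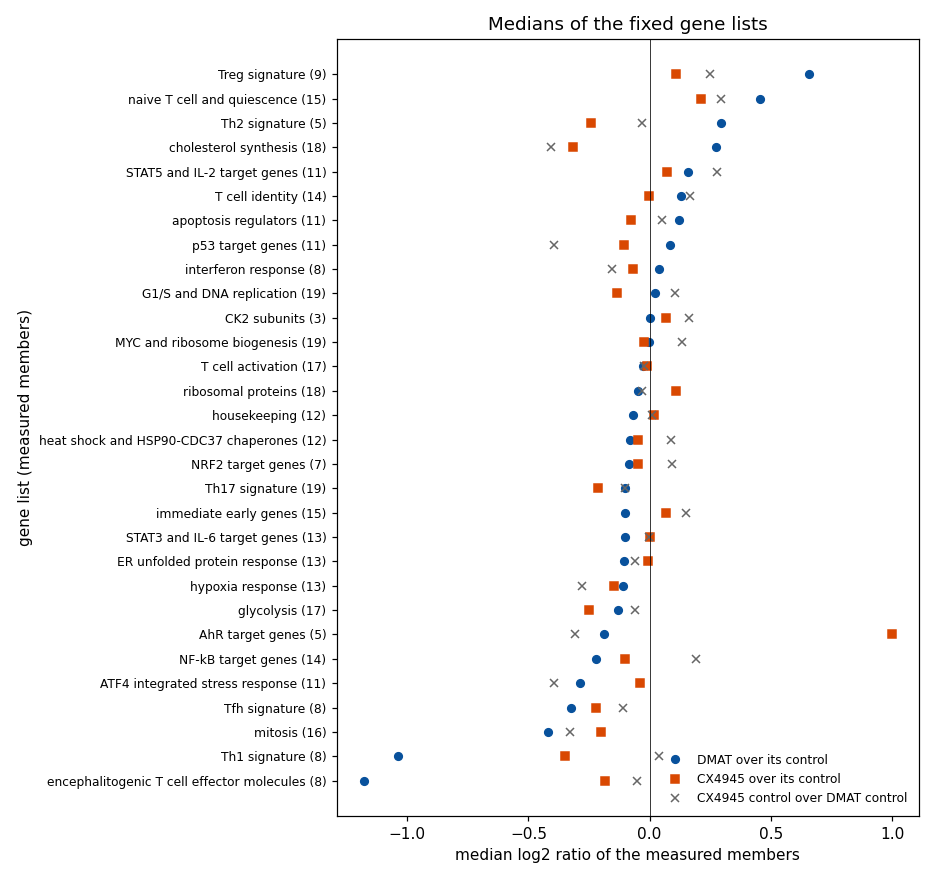
Median log2 ratio of each gene list with at least 3 measured members, for DMAT over its control, CX4945 over its control, and the control for CX4945 over that for DMAT. Th1 and encephalitogenic effector genes lie lowest with DMAT, at -1.04 and -1.18, and cholesterol synthesis genes lie at 0.27 with DMAT and -0.32 with CX4945.

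The T cell activation list did not pass the camera test of the joint fit (0.538), in which shifts of opposite sign cancel. Its medians were -0.03 and -0.01, 0 of 17 genes passed over all genes, and 3 rose and 5 fell when adjusted over the list alone. Cd44, an activation marker, stood at -0.77 and -0.54 (adjusted p = 0.0694) and Cd69, an early activation marker, at 0.49 and 0.21 (0.176). Immediate early genes did not pass it (0.925), with medians of -0.10 and 0.07 and Klf6 falling, nor did STAT5 and IL-2 target genes (0.312; 0.16 and 0.07), interferon response genes (0.286; 0.04 and -0.07) or apoptosis regulators (0.333; 0.12 and -0.08). The same was true of G1/S and DNA replication genes (0.618; 0.02 and -0.13), MYC and ribosome biogenesis genes (0.78; 0.00 and -0.02), p53 target genes (0.579; 0.08 and -0.11), ER unfolded protein response genes (0.925; -0.11 and -0.01), chaperones (0.255; -0.08 and -0.05), NRF2 target genes (0.328; -0.08 and -0.05), AhR target genes (0.618; -0.19 and 1.00), CK2 subunits (0.814; 0.00 and 0.07), ribosomal proteins (0.78; -0.05 and 0.11), housekeeping genes (0.834; -0.07 and 0.02) and cholesterol synthesis genes (0.834; 0.27 and -0.32). Histone genes did not pass it (0.921). Per inhibitor, some of these lists did have a median outside the central 95% of matched random lists: cholesterol synthesis genes with both inhibitors, on opposite sides, G1/S, ribosomal protein and AhR target genes with CX4945, and Th2 and STAT5 target genes with DMAT. Il22 fell in the AhR list. Adjusted over the list alone, 3 STAT5 target genes rose and 1 fell, 1 AhR target gene rose and 1 fell, 1 apoptosis regulator rose, and 1 gene fell in each of the immediate early, interferon, ribosomal protein and housekeeping lists. For AhR, immediate early, ER, ribosomal protein, housekeeping and cholesterol genes the median, the mean and the test of the joint fit differed in sign.

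Markers of other cells were nearly absent. No B cell, myeloid, CD8 T cell, NK cell or erythroid marker reached 20 reads in both pairs. Of the antigen-presenting cell list Cd74, the MHC class II invariant chain, alone did, with 23 and 7 reads in the DMAT pair and 34 and 34 in the CX4945 pair.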

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

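The tests of explanations in this part were chosen after the results were seen, while the gene lists and their medians were planned. Cholesterol synthesis genes stood out because they stood on opposite sides of 0 with the inhibitors: the median of 18 genes was 0.272 with DMAT and -0.317 with CX4945, outside the ranges of matched random lists, and the difference was not tested. Reads shared between paralogs do not account for it, since with unique reads the medians lay 0.595 apart on the log2 scale, still on opposite sides. The difference between the controls stays open: they differed by -0.41 in this list, and against the mean of both controls the medians lay 1.08 apart, but that gap also carries the difference between the experiments and so excludes nothing. Control, experiment and compound cannot be told apart here, and each may be the cause.

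Lars2 and AY036118 rose with both inhibitors. The exon-exon reads of Lars2 were 1.44 times as frequent with the inhibitors (95% counting interval 0.893 to 2.34) and its other exon reads 3.3 times (2.98 to 3.65), which argues against a rise of spliced Lars2 mRNA as the whole cause. The AY036118 transcript matched a transcript of the searched set over all 923 bases. That set held transcripts annotated as ribosomal RNA and those of Gm42418, added by name, and which of them matched was not recorded. Ribosomal RNA carried in the libraries is thus a candidate source of the AY036118 reads, not an established one. Lars2 shared 0 bases with the 357 searched transcripts. The longest of these had 1849 bases and no nuclear large subunit RNA was among them, so that source stays open for Lars2. Whether the inhibitors change ribosomal RNA in the cell was not tested.

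Of the 5 Th17 genes that fell, the highest log2 ratio with either inhibitor was -1.1 (Il1r1 with DMAT). A lower share of T cells as a whole does not account for this, since the lowest T cell identity gene, Lck, stood at -0.262. The shares of subsets among the T cells are not measured by these genes. Weaker activation stays open. The lowest activation gene, Cd44, stood at -0.775, above these 5 Th17 genes, but they were picked because they fell. Medians of the whole Th17 list, -0.10 with DMAT and -0.21 with CX4945, lay above Cd44. Naive, glycolysis and mitosis genes had medians outside matched ranges with both inhibitors, on the side that weaker activation would give. So had NF-kB targets with DMAT. Against the other inhibitor's control the naive median with DMAT turned to -0.0407. An effect of CK2 inhibition on the Th17 programme, which the design names, is open alongside it.

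Reads outside exons, which the comparisons do not use, made up 12.86% of gene reads with DMAT against 12.63% in its control and 12.96% with CX4945 against 12.41%. The controls also differed from each other beyond their Wilson 95% intervals (12.6 to 12.67 and 12.37 to 12.45), by about as much as DMAT from its control and by less than CX4945 from its own. With 1 library each, the spread between libraries of a group is not known.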

How the results depend on the processing

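Alternatives were fixed before the data were examined, except unique reads and total-count scaling of the joint fit, which were added after seeing the data. The number of 2-fold genes depends on the read minimum by construction. Without a filter it was 765 with DMAT, 1082 with CX4945, 951 between the controls and 85 for both inhibitors; with at least 100 reads it was 41, 26, 31 and 5. With a prior count of 5 the controls differed at 136 genes. With the other inhibitor's control 364 genes were counted for CX4945, with the mean of both controls, which both ratios then share, 29 for both inhibitors, and with unique reads 108 for CX4945. Other pseudocounts for the joint fit were not run, since the values were counts. Other counts stayed within 1.5 times, but the genes counted could differ. With the other inhibitor's control 330 genes were counted for DMAT, of which 93 were among the 228 of the main setting. For both inhibitors it gave 15 genes, of which 8 were among the main 18. With DESeq2 size factors all 228 genes for DMAT stayed. The joint count is unstable: 1 gene with no replicate block, 3 with DESeq2, 84 with DESeq2 size factors, 101 with total-count scaling and 108 with unique reads, against 54, and 1 to 73 when each library was left out in turn without the block. The lone library left in an arm is then assumed to vary like the other groups. Of the 54 genes 44 were called under each of 4 other blocked edgeR settings, and Il17f alone was also called without the block and by DESeq2. Without the block, with each library left out in turn, Ltb ranged from -0.0263 (without the CX4945 library) to 1.74. The 12 list calls were kept without the block, with DESeq2 size factors and with unique reads, and 0 with an estimated correlation. That last setting has 1 residual degree of freedom, so hardly any list could pass it. With the other inhibitor's control 9 of 28 list medians stayed, 15 moved, some across 0 from inside their matched ranges (hypoxia with DMAT, NF-kB and T cell identity with CX4945), and 4 from outside those ranges turned sign, all with DMAT, for Treg (-0.0849), naive (-0.0407), ATF4 (0.127) and T cell identity genes (-0.0543); the cause was not tested. Depth limits Il17a, Il22, Foxp3, Il10 and Csf2.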

Other observations

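The test in this part was chosen after the results were seen. Since Actg1, which encodes a cytoplasmic actin, fell in the joint fit (log2 -0.47, with 0.77% of its reads unique, a gene chosen after its values were seen), lower transcription by SRF, a regulator of actin genes, was taken as a hypothesis. Over 20 SRF target genes other than Actg1, Srf and Vcl, the median log2 ratio was 0.084 with DMAT and 0.05 with CX4945, and 3 of the 20 were lower with both, so the hypothesis was not borne out. The controls differed by 0.22 in the same direction. In the same list camera gave p = 0.14 upwards (0.354 with an estimated correlation), and 0 genes passed in either direction.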
